A study of Mus musculus with 196 samples.

How the data were processed

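Formalin-fixed, paraffin-embedded liver sections of 24 mice on 4 slides were imaged by CosMx with a panel of 1000 gene probes and 10 negative-control probes. Each of the 196 deposited samples was 1 field of view of 1 animal, and the fields of an animal were treated as parts of that animal. The deposited expression tables held raw transcript counts per segmented cell and probe, as whole numbers with no normalization, with 1 entry per field of view for transcripts outside cells, which was left out. The deposited metadata gave the mean intensity of each stain over the cell in scanner units (PanCK, the membrane stain B2M, CD45, DAPI, and CD3 or, on slide 9, CD68), with no normalization stated, and the cell area in image pixels. Decoding of barcodes, cell segmentation and their versions were not given in the sources used here, and Seurat was named by the submitters without a version or a role. Tables of single transcripts, cell outlines and field corners were not used, since the counts were already summed per cell. Per the labels, 3 fields on slide 9 were noted as immune infiltrate and 2 fields of old vehicle animal 1 as placed elsewhere than planned, and how the other fields were chosen was not given in the sources used here.

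The groups were 6 of males on slides 5, 6 and 7 (Rosa26KO, p53KO and PtenKO, young and old, 1 animal of each per slide, n = 3) and 3 of wild-type females on slide 9 (young vehicle, old vehicle and old HDM201, n = 2). Males and females shared no slide and were fitted separately, so that sex, slide and treatment were never compared across the sets. The 50 probes listed at 0 in every cell of slide 9 carried no information there. Cells with fewer than 20 transcripts were removed, which left 38401 of 38649, 37996 of 38180 and 33231 of 33473 cells on slides 5, 6 and 7 and 41971 of 42450 on slide 9. Transcripts per animal ranged from 897371 to 4125882, and their number limits counting precision only. For genes near the negative probes the non-specific signal of the probes adds to the count.

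Counts were summed per animal over its remaining cells. A gene was tested where its total lay above the mean plus 2 SD of the negative-control probes, which gave 674 genes in males and 410 in females. Differences were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization) and Benjamini-Hochberg adjustment at a false discovery rate of 0.05, 12 comparisons in all. The fit of the 18 males had a term for each group and for slide, with 10 residual degrees of freedom and a biological coefficient of variation of 0.104. The fit of the 6 females had a term for each group, with 3 residual degrees of freedom and a coefficient of 0.175. Printed log2 fold changes are the fitted coefficients with their SE, and group levels are counts per 10000 transcripts of the tested animals. Comparisons, tests, gene lists, cell type markers and most alternatives were fixed before the data were examined.

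In each comparison the genes named were up to 10 of the largest rises and up to 10 of the largest falls among genes that passed and changed the same way on all 3 slides (males) or had groups that did not overlap (females). Where fewer than 5 genes passed, the 5 of smallest p were given as values. Trp53, Pten, Mdm2 and Cdkn1a were named in the comparisons of p53KO, PtenKO or HDM201 where on the panel, and up to 4 members of smallest p were named from each list described. Within cell classes the genes named were chosen after their values were seen.

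Gene lists (20 by function and 16 of cell type markers) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation, where at least 3 members were tested, which held for 29 lists in males and 24 in females. Beside this, members were counted after Benjamini-Hochberg adjustment over the list alone. No list held with an estimated correlation in any comparison, the lowest adjusted p being 0.0826 in all cells and 0.138 in hepatocyte-like cells.

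Cells of all slides were clustered in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0): log counts scaled to the median depth, each gene centred within slide, 30 principal components, 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Of the clusters, 16 held at least 50 cells, and 20 cells fell outside them. A cluster was named for a non-hepatocyte list where at least 3 of its markers reached a fold of 1.25, with a mean log2 fold of 1 and a margin of 0.5 over the next list. For the hepatocyte list, the main cell type, 3 markers and a mean above 0 with no margin were enough, and the 4 clusters so named had mean log2 folds of 0.258, 0.488, 0.367 and 0.412. These thresholds were set after the clusters were inspected, whereas the markers were fixed earlier. Clusters with 64373 cells, 42.5% of those kept, stayed unnamed. The classes are called by the lists that named them, with the ending -like, and were not checked against any annotation by the authors. Within macrophage-like, endothelial-like, stellate-like and cholangiocyte-like cells the edgeR test was repeated on sums per animal and class, and B-lineage-like cells were too few in some animals, with 9 cells in the lowest. Neighbouring cells can share transcripts through segmentation, so a gene changed within a class can come from cells beside it.

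Class shares, median transcripts per cell and median cell area were compared in males between animals of the same slide by exact two-sided sign-flip tests, over 9 pairs for age and 6 for each genotype, with Benjamini-Hochberg adjustment within a comparison. The smallest p these allow is 0.00391 and 0.0312. Females gave values alone, since 2 animals against 2 cannot pass. Fold changes of pairs of comparisons were correlated across genes, with 100 simulated data sets of unchanged groups for the pair that shares animals.

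Alternatives were RLE size factors, scaling by total counts alone, no gene filter, DESeq2 1.42.0, fits of the compared groups alone, all segmented cells, hepatocyte-like cells alone, no slide block in males, the animal number as a block in females, and each animal left out in turn. For shares and lists they were other Leiden resolutions, a higher transcript minimum, no centring and an estimated correlation. Added after the data were seen were a filter at 3 times the negative-probe mean, a crossed pairing of old females, the cluster led by MHC class II genes, the share of cells high in CD45 stain, sums without the fields noted as immune infiltrate, first with the genes filtered anew and then with the main gene set, an estimated correlation for lists in hepatocyte-like cells, Pten less the negative-probe level, and acute phase genes without 1 old female. The pipeline was tested on simulated data. With the males' size and spread 53.0%, 88.1% and 100% of genes changed by log2 0.25, 0.5 and 1 were recovered, and 10 of 459 unchanged genes were called. With the females' size 4.84%, 44.7% and 86.4% were recovered, and 2 of 206 unchanged genes were called. Figures were drawn with matplotlib 3.10.9.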

Results

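Liver sections of 24 C57BL/6J mice were profiled by CosMx spatial molecular imaging, in which fluorescent barcodes are read by microscopy to count single transcripts inside segmented cells of formalin-fixed, paraffin-embedded tissue. The panel held 1000 gene probes and 10 negative-control probes. Each of 3 slides (5, 6 and 7) carried 1 young and 1 old male of each of 3 untreated genotypes, named in the labels as Rosa26KO, p53KO and PtenKO, so that each male group held 3 animals. Rosa26 is a locus without a required function, and its knockout was taken as the control for the other genotypes. Slide 9 carried 6 wild-type females, 2 in each of the groups young vehicle, old vehicle and old HDM201. HDM201 is an inhibitor of MDM2, the protein that marks p53 for degradation. The ages behind "young" and "old" and the dose and schedule of HDM201 were not given in the sources used here. The labels noted 3 of the fields of view on slide 9 as immune infiltrate, 1 in each HDM201 animal and 1 in old vehicle animal 2, and no field of a male animal. In total 196 fields of view held 152752 cells, of which 151599 had at least 20 transcripts and were kept. Transcripts per animal ranged from 897371 in young vehicle animal 1 to 4125882 in Rosa26KO old animal 2423. The median number of transcripts per cell was 390, 372 and 424 on slides 5, 6 and 7 and 192 on slide 9, and 50 of the 1000 gene probes, Pten among them, were listed at 0 in every cell of slide 9. Levels are given as counts per 10000 transcripts of an animal, as mean ± SD with n = 3 per male group and n = 2 per female group, and fold changes as log2 ± SE.

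The first question was what age changed in the control genotype. In old Rosa26KO livers Fasn, the fatty acid synthase, rose by 1.19 ± 0.24, from 6.84 ± 0.626 to 15.6 ± 4.34 per 10000. Ldlr, the receptor that takes up low-density lipoprotein, rose by 0.41 ± 0.08, to 9.43 ± 0.895. Cd163, a scavenger receptor of resident macrophages, fell by 0.46 ± 0.10, from 9.80 ± 0.480 to 7.14 ± 0.296, and the class I-like gene H2-Q2 fell by 0.28 ± 0.06. Both genes that fell and 1 of the 2 that rose lay under 3 times the mean of the negative probes, which was 3.18 per 10000 in Rosa26KO old and 4.16 in Rosa26KO young, a log2 ratio of -0.39. These 4 were the genes called among 674 tested, each with adjusted p = 0.0358 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Zbtb16 had a log2 fold change of -0.35 with adjusted p = 0.0859. Of 11 genes of lipid synthesis and storage 2 rose, 7 when adjusted over the list alone, and Srebf1 (0.60) and Insig1 (0.43) were among the others of smallest p. The list passed the camera test upward at the preset correlation and had adjusted p = 0.333 with an estimated correlation. Of 9 hepatocyte markers 0 passed over all genes and 1 when adjusted over the list alone, with Apoa1 at 0.97 and Arg1 at 0.59, and the list was called upward (adjusted p = 0.870 with an estimated correlation). Of 11 markers of Kupffer cells, the resident macrophages of the liver, Cd163 fell and the other 10 did not pass, 1 when adjusted over the list alone, with Cd5l at -0.55 and C1qa at -0.33, and the list was called downward (adjusted p = 0.870 with an estimated correlation). The count was 0 without old animal 2423 or without young animal 2421, 2433 or 2437, and 2 without old animal 2431. Scaled by total counts alone, 1 gene rose and 0 fell.

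With age in livers labelled p53KO, after the tumour suppressor p53, 54 genes passed. Among them Cd74, the invariant chain of MHC class II, rose by 1.5 ± 0.32, from 31.3 ± 11.9 to 89.1 ± 24.3 per 10000, H2-Aa by 1.34 ± 0.27, H2-Ab1 by 1.12 ± 0.28 and H2-Eb1 by 1.06 ± 0.23. Cd52, a surface glycoprotein of lymphocytes, rose by 0.97 ± 0.15 (from 7.33 ± 0.429 to 14.5 ± 3.62), the chemokines Cxcl9 by 0.91 and Ccl5 by 0.84, and Cotl1, an actin-binding protein, by 0.85. Igkc, the kappa light chain of antibodies, rose by 2.75 ± 0.65 and Ighm, the mu heavy chain, by 2.35 ± 0.69. Their spread was wide, since Igkc stood at 65.5 ± 87.1 per 10000 in the old animals, and without old animal 2444 their log2 fold changes were 1.08 and 0.39 and did not pass. Cd163 fell by 0.61 ± 0.10, from 9.78 ± 0.254 to 6.42 ± 0.108. Rgs5, a pericyte gene, fell by 0.49 ± 0.13, Pgr by 0.37, Cdh11 by 0.27, the hepatocyte growth factor Hgf by 0.26, Ica1 by 0.26, Prox1 by 0.25, Wnt9a by 0.23, Cyp2u1 by 0.22 and Acvr2a by 0.21. Of the 12 genes that fell 11, and of the 42 that rose 26, lay under 3 times the mean of the negative probes, which was 2.90 per 10000 in p53KO old and 3.65 in p53KO young. Trp53 (0.14, adjusted p = 0.196 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Cdkn1a, a cell cycle inhibitor induced by p53 (0.17), and Pten (-0.02) did not pass.

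By list, 5 of 6 genes of MHC class II presentation rose between young and old p53KO animals, 6 when adjusted over the list alone (adjusted p = 0.347 with an estimated correlation). Of 10 genes of the NF-kB response 4 rose, 6 when adjusted over the list alone, among them the monocyte chemokine Ccl2 at 0.68, Icam1 at 0.37, Il1b at 0.35 and Nfkbia at 0.32 (adjusted p = 0.347 with an estimated correlation). Of 15 genes of the interferon response 3 rose, both over all genes and when adjusted over the list alone, with Cxcl9, Stat1 at 0.52 and Oas3 at 0.38 (adjusted p = 0.934 with an estimated correlation). In all, 42 genes rose and 12 fell. The count of 54 was 12 without old animal 2452, 97 without old animal 2456, 27, 8 and 21 without young animals 2442, 2446 and 2450, and 1 in hepatocyte-like cells alone. With scaling by total counts alone 20 rose and 2 fell.

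In livers labelled PtenKO, after the lipid phosphatase that opposes PI3K signalling, Cd163 was the gene called with age: it fell by 0.76 ± 0.10, from 9.41 ± 0.866 to 5.57 ± 0.986 per 10000 (adjusted p = 0.000519, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The genes of next smallest p were Nanog at -0.26 (adjusted p = 0.0544), Zbtb16 at -0.38, G0s2, an inhibitor of triglyceride breakdown, at -0.78 and Pgr at -0.33. Pten (0.04), Trp53 (-0.06) and Cdkn1a (-0.18) did not pass. Of 6 genes of MHC class II presentation 0 passed over all genes and 5 when adjusted over the list alone, with Cd74 at 1.09, H2-Aa at 1.04 and H2-Ab1 at 1.02 (adjusted p = 0.925 with an estimated correlation). Of 7 genes of MHC class I presentation 0 passed in either way (adjusted p = 0.959 with an estimated correlation). At an unadjusted p under 0.05, 96 genes were counted, and DESeq2 called 22. The count of 1 was 5 without old animal 2424, 10 without old animal 2428 and 2 without young animal 2422. It was 0 in hepatocyte-like cells, 0 in the fit of the compared groups alone, where Cd163 stood at -0.77 with adjusted p = 0.186, and 0 among genes at 3 times the negative-probe mean, which Cd163 did not reach.

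**Figure D1:**
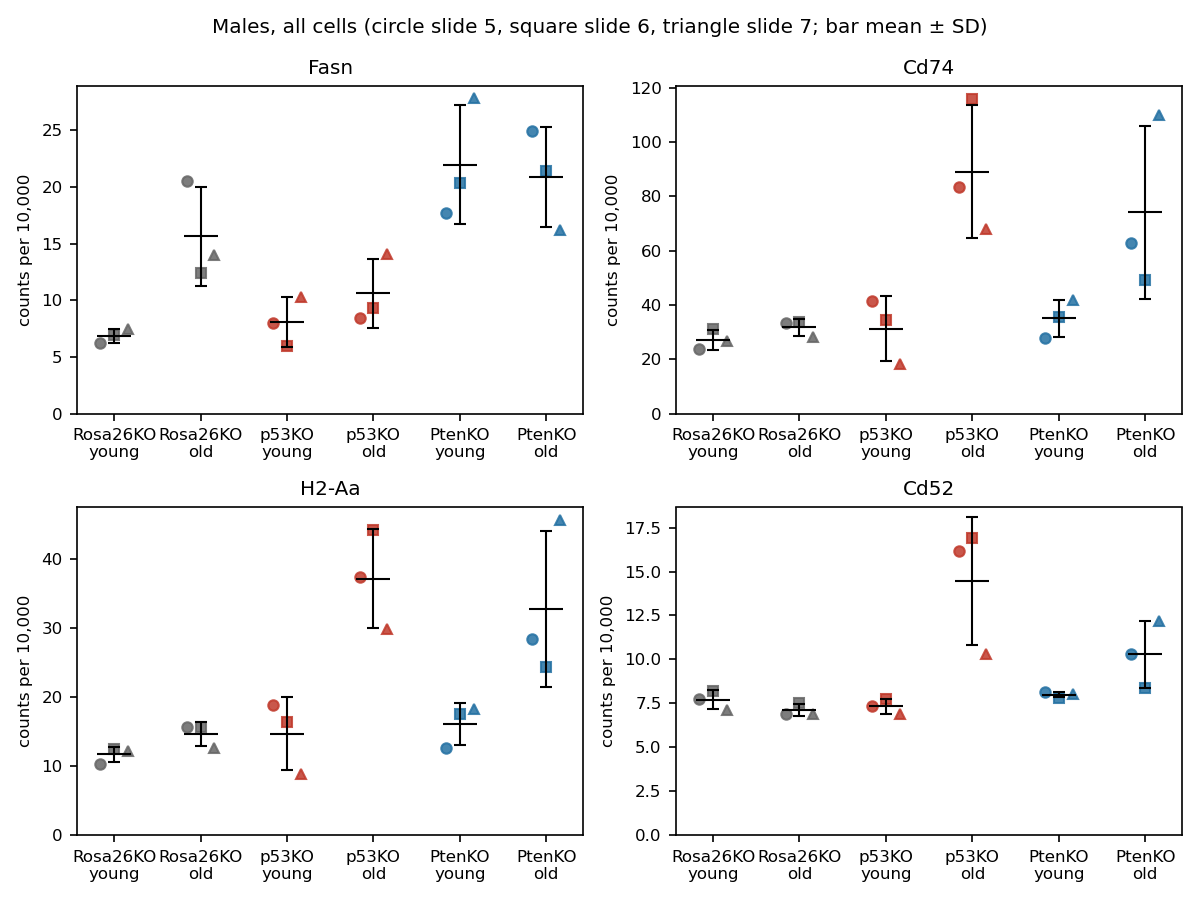
Counts per 10000 transcripts of Fasn, Cd74, H2-Aa and Cd52 in the 6 male groups, with 1 point per animal and the mean ± SD of the 3 animals. Cd74 lies at 89.1 ± 24.3 in p53KO old and 74.1 ± 31.9 in PtenKO old against 31.7 ± 3.16 in Rosa26KO old, and Fasn at 22.0 ± 5.25 in PtenKO young against 6.84 ± 0.626 in Rosa26KO young.

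The next question was what loss of p53 changed at each age. Trp53 itself was no lower in p53KO animals: its level was 5.12 ± 0.393 per 10000 in p53KO young against 4.76 ± 0.452 in Rosa26KO young and 5.62 ± 0.396 against 5.46 ± 0.308 in old animals, with log2 fold changes of 0.11 ± 0.07 and 0.04 ± 0.06. These levels lay close to those of the negative probes. The negative probes stood at 3.65 per 10000 in p53KO young, 4.16 in Rosa26KO young, 2.90 in p53KO old and 3.18 in Rosa26KO old. A loss of Trp53 could go unseen so near that level. Where on the transcript the probes bind was not given in the sources used here and a probe outside the deleted part checks nothing about the deletion. In young animals 0 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 53 at an unadjusted p under 0.05 and 3 called by DESeq2. The genes of smallest p were Junb at 0.34 ± 0.09, Dst at -0.21, Xbp1 at 0.44, Celsr1 at -0.19 and Mcpt8 at -0.29, with adjusted p between 0.423 and 0.434. Cdkn1a was at -0.30 (adjusted p = 0.633) and Pten at 0.21 (adjusted p = 0.554). Lists called at the preset correlation were the interferon response downward (15 genes, with Ifit1 at -0.32 and Oas3 at -0.21; adjusted p = 0.682 with an estimated correlation), oxidative stress (7 genes, with Mt1 at 0.40; adjusted p = 0.682 with an estimated correlation) and hepatocyte markers (9 genes, with Igf1 at 0.40; adjusted p = 0.682 with an estimated correlation) upward. Components of the PI3K and mTOR pathway (4 genes) and immediate early genes (9 genes, Junb passing when adjusted over the list alone) were also called upward, each with adjusted p = 0.404 with an estimated correlation. In the other 4 lists 0 members passed when adjusted over the list alone.

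In old animals 81 genes passed between p53KO and Rosa26KO livers. Cd74 rose by 1.48 ± 0.32, to 89.1 ± 24.3 per 10000 from 31.7 ± 3.16, H2-Aa by 1.34 ± 0.27 (37.1 against 14.7), H2-Ab1 by 1.18 ± 0.28 (43.6 against 19.0) and H2-Eb1 by 1.14 ± 0.23. The chemokine Cxcl9 rose by 1.04 ± 0.18, Cd52 by 1.02 ± 0.15, Ccl5 by 0.99 ± 0.24, Cd5l, a protein secreted by Kupffer cells, by 0.87 ± 0.22 (34.2 against 18.9), the galectin Lgals3 by 0.84 and Plac8 by 0.82. Ttr, the thyroid hormone carrier made by hepatocytes, fell by 0.89 ± 0.26, from 936 ± 290 to 501 ± 44.6 per 10000. The other falls were smaller: Col18a1 by 0.51, Ceacam1 by 0.39, Hsd17b2 by 0.35, Dpp4 by 0.33, Pgr by 0.33, Il1rap by 0.32, Epha7 by 0.28, Ldlr by 0.28 and Agr2 by 0.26. Of the 18 genes that fell 14, and of the 63 that rose 39, lay under 3 times the mean of the negative probes, which was 2.90 per 10000 in p53KO old and 3.18 in Rosa26KO old. Cdkn1a was at -0.04 and Pten at 0.07, and neither passed. Adjusted p was 0.00885 for Cd74, 0.00138 for Cd52 and 0.0350 for Ttr by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

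Among the lists in old p53KO against old Rosa26KO livers, 5 of 6 MHC class II genes rose, 6 when adjusted over the list alone, including H2-DMa at 0.52 (adjusted p = 0.333 with an estimated correlation). Of 10 NF-kB genes 6 rose, 7 when adjusted over the list alone, with Ccl2 at 0.58, Il1b at 0.43, Icam1 at 0.43 and Nfkbia at 0.40 (adjusted p = 0.234 with an estimated correlation). Of 16 genes of the secretory phenotype of senescent cells 5 rose, also 5 when adjusted over the list alone (adjusted p = 0.361 with an estimated correlation). Of 11 Kupffer cell markers 6 rose, 7 when adjusted over the list alone, with C1qc at 0.78, C1qa at 0.73 and Cd68 at 0.50 (adjusted p = 0.792 with an estimated correlation). Together 63 genes rose and 18 fell. The count of 81 was 33, 50 and 28 without old Rosa26KO animals 2423, 2431 and 2439, 20 without old p53KO animal 2452, and 5 in hepatocyte-like cells alone. Under total-count scaling 62 rose and 6 fell.

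Loss of Pten was examined in the same way. Pten did not pass in young animals, at 8.38 ± 0.435 per 10000 in PtenKO against 9.70 ± 0.698 in Rosa26KO (log2 fold change -0.21 ± 0.08, adjusted p = 0.0924 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In old animals it fell by 0.29 ± 0.08, to 8.65 ± 0.671 against 10.5 ± 1.21 (adjusted p = 0.0311 in the same edgeR test). With the level of the negative probes taken off, Pten was at 5.49 ± 0.609 in PtenKO young against 5.53 ± 0.686 in Rosa26KO young and at 6.04 ± 0.795 against 7.35 ± 1.65 in old animals. In hepatocyte-like cells alone it fell by 0.41 in young and by 0.46 in old animals. The binding sites of the Pten probes were not given either, so the remaining signal does not measure how much of the gene was deleted. In young PtenKO livers Fasn rose by 1.67 ± 0.24, from 6.84 ± 0.626 to 22.0 ± 5.25, the cholesterol synthesis gene Hmgcs1 by 1.07 ± 0.32, the fatty acid transporter Cd36 by 0.97 ± 0.19, the glycolytic genes Eno1/b by 1.07 ± 0.24 and Ldha by 0.95 ± 0.21, Atp5b of the ATP synthase by 1.04 ± 0.27 and glutamine synthetase Glul by 0.96 ± 0.29 (from 27.5 to 53.3). The galectin Lgals1 rose by 1.08, S100a10 by 1.07 and Rarres1 by 1.00. Trp53, whose level in Rosa26KO young lay close to that of the negative probes, rose by 0.28 ± 0.07. Cdkn1a was at 0.33 with adjusted p = 0.122 in the same edgeR test. Falls were between 0.37 and 0.29 among the largest: Il10 by 0.37, Fgf7 by 0.34, Mcpt8 by 0.33, the cytotoxic granule protease Gzmb by 0.33, H2-Q2 by 0.32, Wnt9a by 0.32, Ins1 by 0.30, Tcap by 0.30, Casr by 0.29 and Rgcc by 0.29. All 46 genes that fell and 23 of the 45 that rose had levels under 3 times the mean of the negative probes, and the negative probes themselves were at 2.89 per 10000 in PtenKO young against 4.16 in Rosa26KO young. With the negative-probe level taken off, the median log2 ratio of the 46 falls went from -0.237 to 0.0688, and 15 of them were still lower.

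Of 11 genes of lipid synthesis and storage 9 rose in young PtenKO livers, 10 when adjusted over the list alone, including Cidea, a lipid droplet protein, at 0.78 and Acacb at 0.60 (adjusted p = 0.0826 with an estimated correlation). Of 5 p53 target genes Gdf15 (0.42) and Bax (0.26) rose, 2 when adjusted over the list alone, and of 5 senescence-associated genes 1 rose, 1 when adjusted over the list alone (adjusted p = 0.577 with an estimated correlation for each list). Oxidative stress genes were called as a list with 0 of 7 members passing in either way, Sqstm1 at 0.65 and Sod2 at 0.38 (adjusted p = 0.717 with an estimated correlation). Of 9 markers of NK cells and cytotoxic lymphocytes 3 fell, also 3 when adjusted over the list alone, namely Gzmb, Xcl1 by 0.22 and Ncr1 by 0.19 (adjusted p = 0.577 with an estimated correlation). These 3 are among the 46 weakly counted falls, whose median log2 ratio went from -0.237 to 0.0688 once the negative-probe level was taken off. In sum 45 genes rose and 46 fell. The count of 91 was 21 and 20 without PtenKO young animals 2430 and 2434 and 21, 46 and 42 without Rosa26KO young animals 2421, 2433 and 2437. Scaled by total counts alone, 21 genes rose and 120 fell. In hepatocyte-like cells alone 124 of 449 tested genes passed, of which 63 rose and 61 fell, and 64 were among the 91.

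Between old PtenKO and old Rosa26KO livers 113 genes passed. Cd74 rose by 1.23 ± 0.32 (74.1 ± 31.9 against 31.7 ± 3.16 per 10000), H2-Aa by 1.17 ± 0.27, H2-Ab1 by 1.09 ± 0.28 and H2-Eb1 by 0.91 ± 0.23. Cd5l rose by 1.10 ± 0.22, Ccl5 by 0.90 ± 0.24, and the complement genes of macrophages C1qc by 0.85 ± 0.19 and C1qb by 0.83 ± 0.21. Glul rose by 1.13 ± 0.30 (71.1 ± 39.2 against 31.7 ± 8.69) and the acute phase protein Saa1/2, a probe shared by paralogs, by 0.92 ± 0.27. Cd163 fell by 0.36 ± 0.10, Pgr by 0.45, Mmp1a by 0.35, Reg1 by 0.34, Ins1 by 0.31, Epha7 by 0.31, Ramp3 by 0.30, Prss2 by 0.30, Adgrg6 by 0.29 and Cdh11 by 0.29. Of the 60 genes that fell 59, and of the 53 that rose 22, lay under 3 times the mean of the negative probes, which was 2.61 per 10000 in PtenKO old and 3.18 in Rosa26KO old. Trp53 (0.03) and Cdkn1a (0.25) did not pass. Adjusted p was 0.0201 for Cd74 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

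List by list, 5 of 6 MHC class II genes rose in old PtenKO livers, 5 when adjusted over the list alone, and 3 of 7 MHC class I genes, 4 when adjusted over the list alone, with H2-D1 at 0.54, H2-T23 at 0.54 and the peptide transporter Tap1 at 0.37. Of 15 interferon genes Stat1 at 0.79 and Cxcl9 at 0.64 rose, of 11 lipid genes Cd36 at 0.71 and Fabp4 at 0.64, each 2 when adjusted over the list alone. Of 11 Kupffer cell markers 5 rose and Cd163 fell, 6 and 1 when adjusted over the list alone. Each of these 5 lists had adjusted p = 0.827 with an estimated correlation. Altogether 53 genes rose and 60 fell. The count of 113 was 31 without PtenKO old animal 2424, 19 without Rosa26KO old animal 2431, 43 without Rosa26KO old animal 2439, and 11 in hepatocyte-like cells alone. Scaled by total counts alone, 23 rose and 1 fell.

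Whether age acted differently in the knockouts was tested with interaction terms. For p53KO 7 genes had a larger change with age than in Rosa26KO: Cd52 by 1.09 ± 0.21, the complement gene C1qa by 1.06 ± 0.24, Ccl2 by 0.77 ± 0.12, the leukocyte phosphatase Ptprc (the gene of CD45) by 0.70 ± 0.14, the integrin Itgal by 0.65 ± 0.14, H2-DMa by 0.61 ± 0.12 and the myeloid kinase Hck by 0.45 ± 0.10. Adjusted p ranged from 0.00422 for Ccl2 to 0.0413 for C1qa by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cdkn1a (0.26), Trp53 (-0.06) and Pten (-0.14) did not pass. Lists called upward were MHC class II (1 of 6, 6 when adjusted over the list alone; adjusted p = 0.467 with an estimated correlation), NF-kB (1 of 10, 6 when adjusted over the list alone; adjusted p = 0.467 with an estimated correlation), the secretory phenotype (1 of 16, 5 up and 1 down when adjusted over the list alone; adjusted p = 0.467 with an estimated correlation), Kupffer cell markers (1 of 11, 7 when adjusted over the list alone) and interferon (0 of 15, 5 when adjusted over the list alone), the last 2 with adjusted p = 0.499 with an estimated correlation. Lipid genes (0 of 11, 1 down when adjusted over the list alone) and hepatocyte markers (0 of 9 in either way) were called downward, also with adjusted p = 0.499 with an estimated correlation. The count of 7 was 1, 3 and 2 without Rosa26KO old animals 2423, 2431 and 2439, 1 without Rosa26KO young animal 2421, 2433 or 2437, 16 and 44 without p53KO old animals 2444 and 2456, 2 without p53KO young animal 2442 and 1 without 2446 or 2450.

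For PtenKO the interaction with age gave 0 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 72 at an unadjusted p under 0.05 and 5 called by DESeq2. The smallest p belonged to Il10rb at 0.31 (adjusted p = 0.142), H2-DMa at 0.50, G0s2 at -0.97, Fasn at -1.24 ± 0.33 and Pld3 at 0.38, and Trp53 was at -0.26, Cdkn1a at -0.09 and Pten at -0.08. The lipid list was called downward, with 0 of 11 genes passing and 4 down when adjusted over the list alone (adjusted p = 0.590 with an estimated correlation). MHC class II (1 of 6 when adjusted over the list alone), MHC class I (0 of 7), interferon (0 of 15) and Kupffer cell markers (4 of 11) were called upward with 0 genes passing over all genes (adjusted p = 0.784 with an estimated correlation for each). Leaving out the animals of these groups in turn gave 0 genes except for 6 without PtenKO old animal 2428.

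In wild-type females age gave 0 genes among 410 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 17 at an unadjusted p under 0.05 and 3 called by DESeq2. Cd163 stood at 9.79 ± 2.52 per 10000 in old vehicle animals against 18.8 ± 1.06 in young ones (log2 fold change -0.94 ± 0.23, adjusted p = 0.819). The globin probe Hba-a1/2 was at 0.51 ± 0.10 (adjusted p = 0.629), Btf3 at 0.41, Cdh1 at -0.34 and Wnt9a at -0.32. Lists called upward were MHC class I (0 of 6 genes) and hepatocyte markers (0 of 9), with 0 members passing when adjusted over the list alone and adjusted p = 0.980 with an estimated correlation for both. Simulated changes of log2 1 were recovered in 86.4% of genes and changes of 0.5 in 44.7% in the comparison of old HDM201 with old vehicle animals, of the same size.

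The question in old females was what MDM2 inhibition by HDM201 changed. The p53 target Cdkn1a rose by 1.14 ± 0.09 against old vehicle, from 8.88 ± 0.0621 to 19.5 ± 0.641 per 10000 (adjusted p = 0.00239, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The pro-apoptotic p53 target Bax was at 0.61 ± 0.11 (19.5 ± 2.24 against 12.8 ± 0.0181, adjusted p = 0.0851), and Trp53 at -0.04. Antibody genes made up the other 3 calls: Igkc rose by 2.55 ± 0.33, from 18.4 ± 7.06 to 108 ± 18.5 per 10000, Ighm by 2.33 ± 0.22 and Jchain, which joins IgM and IgA chains, by 1.56 ± 0.14. Without the 3 fields noted as immune infiltrate Igkc was at 0.38 ± 0.17, Ighm at 0.21 ± 0.13 and Jchain at -0.09 ± 0.09, none passing, while Cdkn1a kept 1.17. Of 4 senescence-associated genes Cdkn1a rose, 1 when adjusted over the list alone, with Bcl2l1 at 0.34 and Igfbp7 at 0.23, and of 3 B cell markers Ighm rose, 1 when adjusted over the list alone, with Cd37 at 0.24 and Ms4a1 at -0.05 (adjusted p = 0.273 with an estimated correlation for both lists). Without the noted fields the B cell list was not called (adjusted p = 0.987 at the preset correlation). The count of 4 was 0 of 297 genes in hepatocyte-like cells alone. This class held 3663 and 661 cells in HDM201 animals 1 and 2 and 938 and 3926 in old vehicle animals 1 and 2. Camera called the senescence-associated list upward there at the preset correlation (adjusted p = 3.85e-05) and not with an estimated correlation (adjusted p = 0.358). The count of 4 was not judged by leaving animals out, since that leaves 1 animal in a group and takes the spread from the others. Mdm2 was not on the panel, and fewer than 3 p53 targets were measured well enough for a test of that list.

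Against young vehicle animals, old HDM201 animals had higher Cdkn1a (1.13 ± 0.09, adjusted p = 0.00177 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Igkc (3.15 ± 0.34), Ighm (2.94 ± 0.23) and Jchain (1.34 ± 0.14), and the protease gene Mmp1a fell by 0.54 ± 0.09, from 13.3 to 9.12 per 10000. Mmp1a and 2 of the 4 genes that rose lay under 3 times the mean of the negative probes, and Mmp1a did not pass without the gene filter or in the fit of the compared groups alone, where 4 genes rose and 0 fell each time. Trp53 was at -0.08. Without the noted fields Cdkn1a was the gene called at 1.16, with Igkc at 0.70, Ighm at 0.54, Jchain at -0.35 and Mmp1a at -0.50. Of 4 senescence-associated genes and 3 B cell markers 1 each rose, 1 when adjusted over the list alone (adjusted p = 0.374 with an estimated correlation for both). Leaving out 1 animal leaves 1 in its group, with the spread taken from the other groups, so the count was not judged that way. Under total-count scaling 7 rose and 1 fell, and in hepatocyte-like cells alone 0 genes passed. Camera called the senescence-associated list upward in those cells at the preset correlation (adjusted p = 0.0278) and not with an estimated correlation (adjusted p = 0.587).

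**Figure D2:**
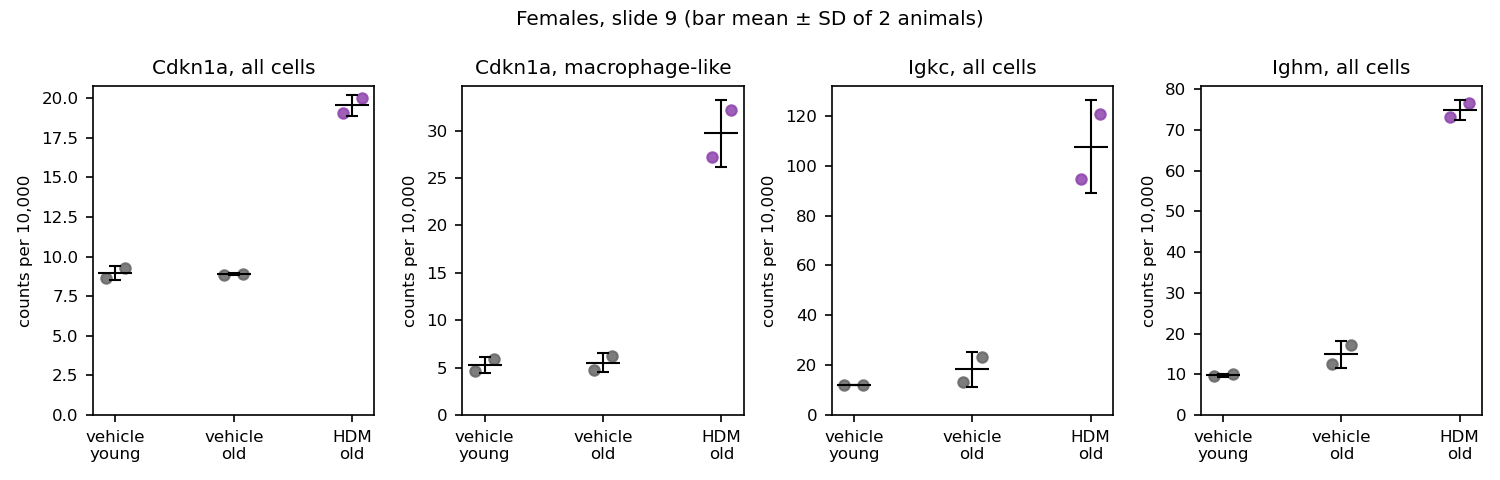
Counts per 10000 transcripts in the 3 female groups of slide 9, with 1 point per animal and the group mean ± SD (n = 2), for Cdkn1a in all cells, Cdkn1a in macrophage-like cells, Igkc and Ighm. Cdkn1a lies at 19.5 ± 0.641 in HDM201 animals against 8.88 ± 0.0621 in old vehicle animals, and Igkc at 108 ± 18.5 against 18.4 ± 7.06, with the fields noted as immune infiltrate included.

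Within macrophage-like cells Cd163 fell with age in all 4 comparisons of old with young. It fell by 1.13 ± 0.22 in Rosa26KO (from 37.0 to 16.9 per 10000 transcripts of these cells), by 1.80 ± 0.22 in p53KO (from 36.7 to 10.6), by 1.94 ± 0.23 in PtenKO (from 31.7 to 8.60) and by 2.50 ± 0.25 in vehicle females (from 55.4 to 9.86), with adjusted p = 0.0216 in Rosa26KO and 5.44e-05 in females by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Old PtenKO animals were lower than old Rosa26KO animals by a further -1.03. HDM201 animals stood at 9.79, next to old vehicle animals. With age in PtenKO, Cd163 was also called downward in endothelial-like (-0.86 ± 0.16) and stellate-like cells (-1.02 ± 0.17), and in neither class with age in Rosa26KO or p53KO. Transcripts of neighbouring cells were not told apart from those of these classes. Cdkn1a rose under HDM201 by 2.45 ± 0.23 in macrophage-like cells (from 5.50 to 29.7), by 1.33 ± 0.16 in endothelial-like cells and by 1.30 ± 0.22 in stellate-like cells. Without the noted fields these values were 2.45, 1.36 and 1.33, and Cd163 with age in female macrophage-like cells was at -2.50. In cholangiocyte-like cells Cdkn1a stood at 1.40 ± 0.34 against old vehicle (adjusted p = 0.130 by the same edgeR test) and rose by 1.96 ± 0.35 against young vehicle animals (adjusted p = 0.000819).

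**Figure D3:**
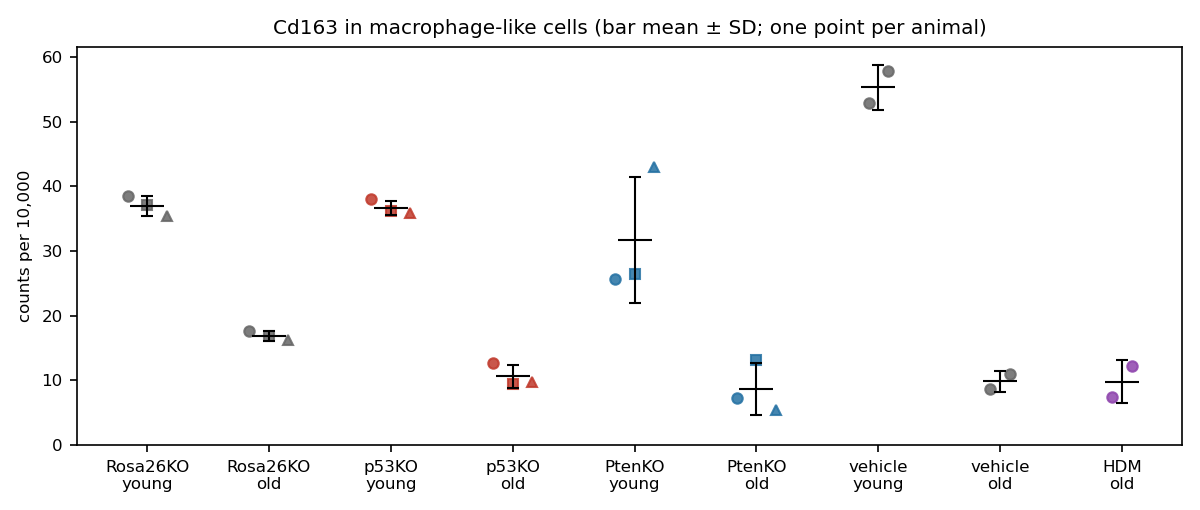
Cd163 counts per 10000 transcripts of macrophage-like cells in the 9 groups, with 1 point per animal and the group mean ± SD (n = 3 in male and n = 2 in female groups). Young groups lie between 31.7 in PtenKO and 55.4 in vehicle females, and old groups between 8.60 in PtenKO and 16.9 in Rosa26KO.

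Genes also passed within other cell classes in old p53KO against old Rosa26KO livers, where transcripts of neighbouring cells were not told apart from those of the class. Stellate-like cells had higher Ccl2 (1.34 ± 0.16) and Cxcl10 (0.92 ± 0.18). Endothelial-like cells had higher Il1a (0.65), Cxcl9 (0.69), Cxcl10 (0.68), Ccl5 (0.91), S100a9 (0.77) and the adhesion molecule Vcam1 (0.53). Cxcl10 fell with age in Rosa26KO in stellate-like (-0.90 ± 0.18) and endothelial-like cells (-0.81 ± 0.15) and was not called with age in p53KO in either class. Cholangiocyte-like cells had higher Fcgbp (1.81 ± 0.38), Igkc (1.83), the matrix protease Mmp7 (1.31) and Lcn2 (1.19) and lower Igfbp3 (-1.02), and macrophage-like cells higher Plac8 (0.91). Ttr was lower in stellate-like (-0.73) and endothelial-like cells (-0.57), which border on the hepatocytes that make it. In young PtenKO livers stellate-like cells had higher collagens Col1a1 (1.32 ± 0.26), Col3a1 (1.07 ± 0.19) and Col1a2 (0.74) with Fasn (1.57) and Rarres1 (1.17), and endothelial-like cells higher Fasn (1.32), Fabp4 (0.82) and Cidea (0.73). Stellate-like and endothelial-like cells also had higher Ttr (0.54 and 0.46), Hmgcs1 (0.79 and 0.70), Glul (0.78 and 0.62) and Eno1/b (0.77 and 0.69). The hepatocyte marker Serpina1a was lower in endothelial-like cells (-0.49). Fasn, Hmgcs1, Glul and Eno1/b also rose over all cells, and transcripts of bordering hepatocytes were not told apart from those of these classes. In old PtenKO livers Ccl5 was higher in macrophage-like (1.62 ± 0.32), stellate-like (0.94) and endothelial-like cells (1.03), Cd36 in endothelial-like cells (1.00 ± 0.13), and Cd74 (1.16), H2-Aa (1.14), Stat1 (1.18) and Lcn2 (1.49) in cholangiocyte-like cells. With age in p53KO, stellate-like cells had higher Ccl2 (1.47 ± 0.16) and Ccl19 (0.77) and lower Hgf (-0.68) and Selenop (-0.58). All of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within their class.

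Cell class shares were compared between animals of the same slide with exact sign-flip tests, two-sided. Endothelial-like cells made up a smaller share in PtenKO than in Rosa26KO animals by -2.49 points (higher in 0 of 6 pairs, exact p = 0.0312, the smallest possible, adjusted p = 0.188), and a smaller share in old than in young animals by -1.27 points (higher in 1 of 9 pairs, exact adjusted p = 0.105), which was -0.289 points without slide 5. The PtenKO difference ran from -3.04 points without slide 7 to -1.54 without slide 6. It was -1.77 points in cells with at least 50 transcripts (higher in 1 of 6 pairs). B-lineage-like cells differed between old and young animals by 2.40 points (higher in 7 of 9 pairs, exact p = 0.0234 where 0.00391 was the smallest possible, adjusted p = 0.105), and by 0.493 points without slide 5 (higher in 4 of 6 pairs, exact p = 0.188). At Leiden resolutions of 0.5 and 2 the difference of this class was 5.14 and 2.36 points (higher in 8 of 9 pairs, exact adjusted p = 0.0469 for each). At 0.5 the class held 8055 cells against 3194 at resolution 1, and no cluster led by MHC class II genes was set apart. The value at 0.5 therefore need not be one of B-lineage-like cells alone. At resolution 1, B-lineage-like cells held 6.63% ± 9.27 of cells in p53KO old animals. This ran from 0.423% in animal 2452 to 17.3% in animal 2444, where 93.8% of them lay in a single field of view. Macrophage-like cells held 7.51% ± 2.96 in p53KO old and 3.21% ± 1.06 in Rosa26KO old animals, and over both ages p53KO minus Rosa26KO was 1.92 points (exact adjusted p = 0.5). At the resolution of 1 used elsewhere no share of a named class passed the adjustment over classes. A cluster led by MHC class II genes was described after it was seen and tested apart from the named classes. It held 7.11% of cells in p53KO old, 6.21% in PtenKO old and 2.30% in Rosa26KO old animals, against 2.03%, 3.07% and 1.92% in the young ones. Its share was higher in old than in young animals by 2.87 points in 8 of 9 pairs (exact p = 0.0117), and differed from Rosa26KO by 2.53 points in PtenKO (higher in 5 of 6 pairs, exact p = 0.0625) and by 2.47 points in p53KO (higher in 4 of 6 pairs, exact p = 0.125). In females B-lineage-like cells held 7.13% ± 0.0672 in HDM201 animals, 1.34% ± 0.346 in old and 0.446% ± 0.117 in young vehicle animals. Without the noted fields the shares were 0.494% and 1.19% in HDM201 animals 1 and 2 and 1.10% and 0.515% in old vehicle animals 1 and 2. Clusters holding 42.5% of cells could not be named from the markers, among them 1 with macrophage markers, which held 5.96% ± 1.06 of cells in p53KO old and 4.71% ± 0.521 in Rosa26KO old animals, and 1 with macrophage and stellate markers together, which held 4.95% ± 1.54 and 3.46% ± 0.701. The largest unnamed cluster had 26712 cells with a median area of 26509 square pixels. Another of 7456 cells was led by Glul (fold 18.4), with a median area of 22613.5. Hepatocyte-like clusters had median areas from 16250 to 31462. Hepatocytes may therefore lie among the unnamed cells, and results in hepatocyte-like cells alone need not cover all hepatocytes.

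Cells were smaller in old than in young males, with a difference in median area of -4235 square pixels (higher in 1 of 9 pairs, exact adjusted p = 0.0156), and smaller in p53KO than in Rosa26KO males by -3806 square pixels (higher in 0 of 6 pairs, exact adjusted p = 0.0312, the smallest possible). p53KO cells held fewer transcripts than Rosa26KO cells, by -60 per cell (0 of 6 pairs higher, exact adjusted p = 0.0312), and PtenKO cells differed by 67.3 per cell (6 of 6 pairs higher, exact adjusted p = 0.0625). With all segmented cells the area of p53KO cells differed by -3779 square pixels and their transcripts by -59.4, each with exact adjusted p = 0.0625. In hepatocyte-like cells alone p53KO minus Rosa26KO was -91.2 transcripts (0 of 6 pairs higher) and -3634 square pixels (1 of 6 pairs higher), and PtenKO minus Rosa26KO was 109 transcripts (5 of 6 pairs higher) and 3308 square pixels (6 of 6 pairs higher), each with exact adjusted p = 0.0625, and old minus young was -2138 square pixels (3 of 9 pairs higher, exact adjusted p = 0.234). The hepatocyte-like class itself was made up of different clusters in different groups: 1 cluster held 72.6% of it in Rosa26KO young, 52.0% in Rosa26KO old and 25.6% in PtenKO young animals, and a cluster led by Mt1, Mt2, Saa1/2 and Lcn2 held 60.2% of it in old vehicle and 64.9% in HDM201 animals, where it came from old vehicle animal 2 and HDM201 animal 1.

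Further lists were called in no comparison of all cells at the preset correlation. In hepatocyte-like cells alone and at the preset correlation camera called the acute phase response upward with age in p53KO (adjusted p = 8.96e-05), in old p53KO (0.000266) and old PtenKO (0.0394) against Rosa26KO and in old HDM201 against young vehicle animals (0.0235), and stellate markers downward with age in p53KO (0.0225), in old p53KO (0.0108) and in the interaction of p53KO with age (0.0142). With an estimated correlation none of the 25 lists called in these cells passed, the lowest adjusted p being 0.138. In HDM201 animals the acute phase gene Saa1/2 stood at 84.8 per 10000 of all cells in animal 1 and 10.2 in animal 2, against 13.1 and 11.5 in young vehicle animals. Without HDM201 animal 1, which leaves 1 animal in that group, its log2 fold change against young vehicle was -0.28. In all cells the lowest adjusted p of camera over the 12 comparisons was 0.0797 for the acute phase response, 0.16 for the unfolded protein response, 0.166 for monocytes, 0.179 for T cells, 0.242 for extracellular matrix, 0.266 for neutrophils, 0.305 for endothelial cells, 0.316 for fetal liver genes, 0.320 for adipocytes, 0.325 for the cell cycle, 0.354 for cholangiocytes, 0.355 for stellate cells, 0.465 for plasma cells and 0.481 for pericentral hepatocyte genes. In the acute phase response Mt1 stood at 2.75 and Mt2 at 2.20 with age in females, both with adjusted p = 0.819 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without old vehicle animal 2 they stood at 0.75 and 0.18, and Mt1 was at 375 per 10000 in that animal and 53.6 in old vehicle animal 1.

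The comparisons were also set side by side through their log2 fold changes across genes, which are not independent replicates. Age in Rosa26KO had r = 0.34 with age in vehicle females over 405 genes, 0.04 with age in p53KO and 0.14 with age in PtenKO over 674 genes. Of the 56 genes called with age in Rosa26KO or p53KO, 30 had the same sign, and these pairs share no animals. Old p53KO against Rosa26KO and HDM201 against old vehicle had r = 0.46, with 39 of 61 called genes of the same sign, but r was -0.00445 and 24 of 59 had the same sign without the fields noted as immune infiltrate. Age in females and HDM201 had r = -0.04 where unchanged groups sharing the old vehicle animals gave -0.50 on average over 100 simulations, and the covariance was -0.00344 against a simulated -0.0285.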

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

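Among the tests below, those of a single animal, of the share of hepatocyte transcripts and of the acute phase spread were written after the results they address were seen, the removal of the noted fields and the CD45 stain were added after the data were seen, and the predictions on probe background were written after the negative-probe levels were seen and before the subtraction.

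A difference between groups was found in 7 genes whose change with age differed between p53KO and Rosa26KO livers by an interaction test: Cd52 (1.09), C1qa (1.06), Ccl2 (0.77), Ptprc (0.70), Itgal (0.65), H2-DMa (0.61) and Hck (0.45). Within classes the same test passed for Cxcl10 in endothelial-like (1.248) and stellate-like cells (1.56), Ccl2 in stellate-like cells (1.52) and Plac8 in macrophage-like cells (1.26). Of 100 splits of the animals, 5 gave 7 genes or more, the highest other split 15. The splits exchanged genotype labels within each age and across slides. Some can therefore carry the difference of old p53KO from old Rosa26KO animals into the interaction. They do not show what chance alone gives, and chance was not excluded for the count.

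A signal in data that the comparisons do not use came from the CD45 stain, a protein of all leukocytes. Cells above the 95th percentile of their slide made up 13.4% ± 5.19 of cells in p53KO old and 7.00% ± 3.34 in PtenKO old animals, against 1.53% in Rosa26KO old animals (n = 3 each). In young animals the share was 1.253% in p53KO, 2.38% in PtenKO and 1.99% in Rosa26KO, and in females 1.10% in young vehicle, 5.70% in old vehicle and 7.58% in HDM201 animals (n = 2 each). The female shares include the 3 fields noted as immune infiltrate and were not computed without them. Since the threshold was set per slide, shares of males and females are not on the same scale. It was taken over all kept cells of a slide, so a high share in 1 animal lowers the shares of the others there. The pairs of a slide are therefore not independent of each other in the exact tests below. The share was higher in old than in young males by 5.42 points in 7 of 9 pairs (exact p = 0.0312), and both pairs that went the other way were Rosa26KO. It was higher in PtenKO than in Rosa26KO by 2.93 points in 6 of 6 pairs (exact p = 0.0312, the smallest possible) and differed between p53KO and Rosa26KO by 5.55 points, higher in 4 of 6 pairs (exact p = 0.219). The stain was above that level in 69.5% of B-lineage-like, 48.4% of MHC class II-leading, 16.9% of macrophage-like and 0.119% of hepatocyte-like cells.

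MHC class II genes rose in old p53KO against old Rosa26KO livers with a list median of 1.16. Animal 2444, with most B-lineage-like cells, was excluded as the source, since the median without it was 1.16. For a lower share of hepatocyte transcripts, the highest median of the endothelial, stellate and cholangiocyte markers was -0.0162. TMM centres most genes near 0, however, and with total counts alone the median of all tested genes was 0.0889. The hepatocyte-like share was 21.5% ± 2.95 in old p53KO and 34.2% ± 6.99 in old Rosa26KO animals, though hepatocytes may lie among unnamed cells. Over both ages p53KO minus Rosa26KO was -4.20 points for this share (exact sign-flip test, adjusted p = 0.5). Stellate-like (4.46% against 7.15%) and cholangiocyte-like shares (1.83% against 2.45%) were also lower in old p53KO animals. The marker medians therefore cannot exclude a lower share of hepatocyte transcripts as part of the source. More macrophage-like cells of unchanged content cannot be told apart from a change within them: inside that class the median was 0.463, with 7 of 7 members positive, but it ran from -0.26 to 0.85 between slides. An effect of p53 loss on leukocyte content or state stays open as a hypothesis and was not tested apart from these.

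The falls in PtenKO against Rosa26KO livers were in weakly counted genes, and the negative probes were lower in PtenKO animals of both ages. After the negative-probe level was taken off, the median log2 ratio of the 46 falls in young animals went from -0.237 to 0.0688, with 15 of 46 still lower, which is consistent with a lower share of non-specific probe signal as their source. For the 60 falls in old animals it went from -0.231 to -0.178, with 60 of 60 still lower, between the values predicted for that source and against it, and the 2 cannot be told apart there. Falls in p53KO were weakly counted too, 11 of 12 with age and 14 of 18 in old animals against Rosa26KO. With age in p53KO the median went from -0.256 to -0.180 with 12 of 12 still lower, which by the same thresholds also cannot be told apart. In old p53KO against Rosa26KO it became larger, from -0.265 to -0.370, with 18 of 18 still lower. The genes were chosen for their falls, and an effect of Pten loss on them stays open as untested.

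Immunoglobulin genes were higher in old HDM201 than in old vehicle females, with a mean of 2.15 over Igkc, Ighm and Jchain. Without the 3 fields noted as immune infiltrate the mean was 0.167. This form keeps the gene set of all fields and replaced a first form, with the genes filtered anew and Jchain lost, after its mean of 0.293 over the other 2 genes was seen. The noted fields held 94.3% and 86.0% of the B-lineage-like cells of HDM201 animals 1 and 2 and 72.4% of those of old vehicle animal 2. The values are consistent with these fields as the source of the rise. Inside them B-lineage-like cells made up 38.3% and 36.0% of cells in HDM201 animals 1 and 2 and 7.65% in old vehicle animal 2, so the noted fields themselves differed, and whether the choice of fields or HDM201 lay behind this was not tested. The acute phase pattern lay in 1 vehicle and 1 HDM201 animal. Igkc in the lower HDM201 animal was 4.04 times that in the higher vehicle animal, noted fields included. This test was written after the rise was seen, so it does not exclude that pattern as a contributor. Taking out B-lineage-like cells left a mean of 0.0810, but this decides nothing, since those cells are defined by the same transcripts.

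Other splits of the same animals were counted for each comparison of 3 animals with 3, where 10 splits are too few for a share under 0.05. The splits exchanged animals across slides, although each slide held 1 animal of each group. As many genes as the real split were given by 1 split, the real one, for age in Rosa26KO (4 genes, highest other 0), age in p53KO (54, highest other 0), age in PtenKO (1, highest other 0), old p53KO against Rosa26KO (81, highest other 1), young PtenKO (91, highest other 0) and old PtenKO (113, highest other 42). For young p53KO against Rosa26KO, with 0 genes, all 10 splits gave as many. For the interaction of PtenKO with age, also 0 genes by edgeR's quasi-likelihood test (72 at an unadjusted p under 0.05, 5 by DESeq2), 100 of 100 splits gave as many, which a real count of 0 fixes beforehand. The highest other gave 197. These splits exchanged genotype labels within each age, so a split that swaps most labels at 1 age carries the genotype difference into the interaction. The source of the 197 was not tested further.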

How the results depend on the processing

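Filters at 3 times the negative-probe mean, the crossed pairing, the sums without noted fields and the estimated correlation in hepatocyte-like cells were chosen after seeing the data. Fields of view with few transcripts per cell for their slide were to be left out, but 0 fields were that low, so that alternative gave no value. For each change below the cause was not tested, except where fewer genes, cells or animals were used by construction.

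Counts of called genes are given against the main value. With scaling by total counts alone they were 1 (main 4) for age in Rosa26KO, 22 (54) for age in p53KO, 2 (1) for age in PtenKO, 141 (91) for young PtenKO, 24 (113) for old PtenKO, 15 (7) for the p53KO interaction with age, 3 (0) for age in females and 8 (5) for old HDM201 against young vehicle. This scaling moved the median of all genes to -0.16 for age in Rosa26KO, -0.23 for young PtenKO, 0.14 and 0.13 for the interactions of p53KO and PtenKO with age, -0.26 for age in females and -0.25 for old HDM201 against young vehicle. RLE size factors gave 2 (1) for age in PtenKO. Without the gene filter the counts were 11 (4) for age in Rosa26KO and 11 (7) for the p53KO interaction.

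The DESeq2 Wald test gave 9 (4) for age in Rosa26KO, 112 (54) for age in p53KO, 22 (1) for age in PtenKO, 3 (0) for young p53KO, 126 (81) for old p53KO, 171 (91) for young PtenKO, 45 (7) and 5 (0) for the interactions of p53KO and PtenKO, 3 (0) for age in females, and 10 (4) and 23 (5) for HDM201 against old and young vehicle. Fits of the compared groups alone gave 22 (4) for age in Rosa26KO, 0 (1) for age in PtenKO, 1 (0) for young p53KO, 39 (81) for old p53KO, 193 (91) for young PtenKO and 16 (7) for the p53KO interaction. With genes at 3 times the negative-probe mean refitted, or adjusted among themselves alone, the counts were 1 and 1 (4) for age in Rosa26KO, 16 and 18 (54) for age in p53KO, 0 and 0 (1) for age in PtenKO, 38 and 32 (81) for old p53KO, 16 and 19 (91) for young PtenKO, 3 and 32 (113) for old PtenKO, 0 and 0 (7) for the p53KO interaction, and 2 and 2 for HDM201 against old (4) and young vehicle (5).

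In hepatocyte-like cells alone the counts were 1 (54) for age in p53KO, 0 (1) for age in PtenKO, 5 (81) for old p53KO, 11 (113) for old PtenKO, 0 (7) for the p53KO interaction and 0 and 0 for HDM201 against old (4) and young vehicle (5). Part of the hepatocytes may lie in unnamed clusters and so outside this class. Without the noted fields HDM201 gave 1 (4) and 1 (5), both with the main gene set and with the genes filtered anew. With the animal number as a block the female comparisons gave 0, 4 and 7, and with a crossed pairing HDM201 against old vehicle gave 4, but the numbers do not show a pairing.

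Leaving out each male gave 0 to 3 genes for age in Rosa26KO, 8 to 97 for age in p53KO, 1 to 10 for age in PtenKO, 0 to 0 for young p53KO, 20 to 106 for old p53KO, 20 to 125 for young PtenKO, 19 to 134 for old PtenKO, and 1 to 44 and 0 to 6 for the interactions of p53KO and PtenKO. In females it leaves 1 animal in a group, so no counts are given. The main counts of 0 came from edgeR's quasi-likelihood test. At an unadjusted p under 0.05 it gave 17 genes for age in females, 53 for young p53KO and 72 for the PtenKO interaction.

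There were 45 list calls, 0 with an estimated correlation, 25 in hepatocyte-like cells and 0 there with an estimated correlation. Class shares had 0 calls, and 1 at each Leiden resolution of 0.5 and 2, the B-lineage-like share with age. At 0.5 that class was wider, with 8055 cells against 3194 in the main clustering. Of 3 calls on transcripts and area, 0 held in hepatocyte-like cells and 1 with all segmented cells. For p53KO the differences were -91.2 transcripts and -3634 square pixels in hepatocyte-like cells and -59.4 and -3779 with all cells (main -60 and -3806), each with exact adjusted p = 0.0625 (main 0.0312). Correlations in hepatocyte-like cells were 0.18 (main 0.34) for age in Rosa26KO and females, 0.44 (0.04) for age in Rosa26KO and p53KO, 0.29 (0.46) for old p53KO and HDM201, and -0.18 (-0.04) for age in females and HDM201, where unchanged groups that share the old vehicle animals gave -0.48 (-0.50). Without noted fields these last were -0.00445 and -0.176.

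Signs reversed as follows, with ranges over the animals left out. With age in p53KO, H2-Eb1 was at -0.040 and Pten at 0.10 in hepatocyte-like cells, and Pten ran from -0.093 to 0.057, positive without 2444 or 2446. With age in PtenKO, Pten was at -0.030 in the refit at 3 times the negative probes and ran from -0.038 (without 2434) to 0.090. In old p53KO, Cdkn1a was at 0.049 under total counts and ran from -0.17 to 0.036 (without 2444), Trp53 from -0.020 (without 2431) to 0.12 and Pten from -0.020 (without 2431) to 0.15. In old PtenKO, Trp53 was at -0.060 under total counts and ran from -0.037 to 0.050, negative without 2428 or 2431, and Cdkn1a ran from -0.048 (without 2424) to 0.42. For Pten, p53KO by age interaction stood at 0.0083 under total counts, and Trp53 was at 0.083 there and ran from -0.13 to 0.010 (without 2456). In the PtenKO interaction Cdkn1a was at 0.0072 and Pten at 0.042 under total counts, and Cdkn1a ran from -0.38 to 0.084 (without 2441). For HDM201 against old vehicle Trp53 was at 0.014 without the gene filter and 0.0020 without noted fields, and Jchain was at -0.088 without noted fields. With females left out in turn, Trp53 ran from -0.0027 to 0.017 (without HDM201 animal 2) where it was tested. Those fits leave 1 animal in a group and filter the genes anew, so the range need not hold the main value. Against young vehicle Trp53 was at 0.023 without the filter and Jchain at -0.35 without noted fields. The Kupffer list turned in hepatocyte-like cells in old p53KO (adjusted p = 0.814) and in the PtenKO interaction (adjusted p = 0.609), and transcripts per cell, old minus young, from -19.1 to 20.1.

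Of the other values, RLE kept 147 and changed 1, all segmented cells kept 152 and weakened 2, the replicate block kept 17, and no slide block kept 122 and weakened 9. Hepatocyte-like cells alone kept 65, weakened 77 and strengthened 2. The fits of the compared groups kept 111, weakened 22 and strengthened 4. Scaling by total counts alone kept 104, weakened 35 and strengthened 3. At the females' size 44.7% of simulated changes of log2 0.5 were recovered, which limits what that set can show.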

Other observations

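The tests of the pairing of females and of the noted fields were added after the data were seen. Animal numbers 1 and 2 recur in the 3 female groups without a statement that they pair animals. Residuals of animals with the same number correlated across genes at 0.57, -0.09 and -0.39 in the 3 pairs of groups, which gave no ground for pairing, and genes are not independent replicates.

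Animals of the same group differed by more than counting error in each of the groups, with chi-square per degree of freedom from 12.2 to 153, summed over all panel genes.

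In p53KO old animal 2444, 93.8% of 1216 B-lineage-like cells lay in 1 of its 7 fields of view, without a note in the labels, and in animal 2456 50.0% of 150 lay in 1 of 9. In old animals of the other male groups the field with most of these cells held between 26.7% and 58.9% of them.

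An unnamed cluster led by macrophage markers held 7.45%, 6.28% and 11.7% of cells in young Rosa26KO, p53KO and PtenKO animals and 4.71%, 5.96% and 9.32% in old ones, and 5.40%, 5.63% and 3.72% in young vehicle, old vehicle and HDM201 animals. An unnamed cluster led by stellate markers held 2.97%, 2.40% and 2.16% in the young and 1.89%, 1.44% and 1.62% in the old male groups.

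The negative probes took 4.16, 3.65 and 2.89 per 10000 counts in young Rosa26KO, p53KO and PtenKO animals, 3.18, 2.90 and 2.61 in old ones, and 6.89, 6.05 and 5.96 in young vehicle, old vehicle and HDM201 animals.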
